A study of Homo sapiens with 6 samples.

How the data were processed

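RNA from 6 cell cultures was measured on 6 Affymetrix arrays, 3 from SUM44 cells given 4-hydroxytamoxifen (4HT) and 3 from LCCTam cells kept without it. Per the labels' protocols, total RNA was extracted with Trizol, cleaned on a column, labelled with biotin by the one-cycle Affymetrix protocol and hybridised. The deposited values are log2 expression levels that the authors made with RMA, which corrects background, quantile-normalises the arrays and summarises each probe set, per the series design text and the submitters' processing notes. The version of RMA was not given in the sources used here. Quantile normalisation gives the arrays nearly equal distributions, so a change in the total amount of RNA per cell would not be seen. The log2 scale was checked against the values, which ran from 3.16 to 14.6, with array medians between 6.70 and 6.77. No detection calls or scanner images were used here, so a dim signal could not be told from background. Gene means had a lower quartile of 5.93 and a median of 7.11.

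Groups were taken from the sample titles. The titles call the arrays biological replicates. Nothing further is said of how the cultures were separated, so the p-values measure the spread between these cultures. The table held 22283 probe sets, of which 68 were Affymetrix controls and were left out of the tests. The platform annotation gave 1 gene to 19065 probe sets, several genes to 1043 and none to 2107, and no gene was named from a probe set with several. Gene symbols were brought up to date by gene ID for 19053 probe sets through the RefSeq gene table of assembly GRCh38.p14, and 12 kept the symbol of the annotation. That table served for names, chromosomes, the order of neighbouring genes and the coding gene density of each chromosome, in coding genes per Mb. The order and the density rest on the gene positions it gives.

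Each gene was represented by its probe set with the highest mean over the 6 arrays, among probe sets annotated to that gene alone, which gave 11963 genes, 4310 of them with more than 1 probe set. Groups were compared with lmFit and eBayes of limma 3.58.1 in R 4.3.3, without an intensity trend or robust fitting. The test was two-sided, p-values were adjusted by the Benjamini-Hochberg method over all genes tested, and genes at an adjusted p under 0.05 were called. The fit had 4 residual and 3.51 prior degrees of freedom. Tested on simulated data of 11963 genes made for this comparison, with 200 genes changed in each of 20 runs, the fit recovered 34.7% of genes changed 1.5-fold, 91.6% of those changed 2-fold and 99.7% of those changed 4-fold. Of its calls, 5.7% were false. A list shifted in the simulation was called in 20 of 20 runs and an unshifted one in 0. The simulated noise was independent between genes, so these results need not hold where genes vary together, as in the real arrays.

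The 19 gene lists, the rule for named genes, the tests and most alternatives were chosen before the data were examined. Lists were tested with camera at a preset correlation between genes of 0.01, adjusted over the 19 lists, and beside it with an estimated correlation and with fry. Members were also counted after adjustment over the list alone. None of the 5 list calls made with the preset correlation held with an estimated one. With an estimated correlation camera uses the 4 residual degrees of freedom of the fit, which leaves little power over 19 lists. A call lost there therefore does not decide whether a list differed. The rule named the 6 genes with the largest higher and the 6 with the largest lower difference among called genes whose groups did not overlap. It further named the 2 members with the smallest adjusted p in each list that had a called member, and always ESR1, PGR, ESRRG, GREB1, TFF1, FOXA1, GATA3 and CDH1. List members named beyond this rule, as examples or to complete a count of 5 or fewer, were chosen after their values were seen. Adjusted p-values of further probe sets of a gene come from a fit of all probe sets other than controls.

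Alternatives changed 1 choice at a time. They were every probe set as its own unit, the mean of a gene's probe sets, an intensity trend with robust fitting, array weights, cyclic loess, centring on array medians, 2 filters on dim genes (genes with a mean above the median of gene means, and genes at a log2 level of 6 or more in all arrays of a group), each array left out, the replicate number as a block, an adjusted p under 0.01, and other segment lengths. Added after seeing the data were a fit with each array's score on the main axis of spread within groups as a covariate, and the tamoxifen metabolism list without its AKR1C genes. The score was computed from the same arrays and takes up 74.6% of their spread within groups. P-values of that fit therefore tend to be too small, and its calls are not an independent check. Chromosome segments were runs of 50 measured genes in chromosome order, tested with camera. The last run of 21 chromosomes held the remainder, so that 216 of 237 runs had 50 genes and the others 31 to 74. With runs of 25 and 100 genes the last ones held 13 to 37 and 51 to 139. Figures were drawn with matplotlib 3.10.9.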

Results

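Gene expression was measured in 6 Affymetrix arrays from a pair of human breast carcinoma cell lines, SUM44 and LCCTam. Both are labelled as invasive lobular lines with estrogen and progesterone receptors. SUM44 is labelled sensitive to tamoxifen, a drug that binds the estrogen receptor, and its 3 cultures were given 500 nM 4-hydroxytamoxifen (4HT), the active metabolite of tamoxifen, for 24 hours. LCCTam is labelled resistant, and its 3 cultures were kept without 4HT for 14 days. Each array is labelled as a biological replicate of its group. The design gives 1 comparison, LCCTam without 4HT against SUM44 with 4HT, in which cell line and drug exposure differ together and cannot be separated. The question it addresses is how the resistant line differs in transcript levels from the sensitive line under the drug. Values are log2 expression levels, differences are LCCTam minus SUM44, and 11963 genes were tested. The number of arrays, 3 per group, limits the precision.

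The 3 SUM44 arrays lay close together, with correlations over genes of 0.994 to 0.995. The LCCTam arrays lay farther apart. Their correlations were 0.982 between replicates 1 and 2, 0.987 between replicates 2 and 3, and 0.958 between replicates 1 and 3. LCCTam replicate 1 correlated with the SUM44 arrays at 0.972 to 0.974, above its correlation with LCCTam replicate 3. The first principal component held 75.6% of the variance and parted the groups, with SUM44 scores of -32.7, -21.4 and -30.2 and LCCTam scores of 4.7, 31.2 and 48.5. Poly-A spike-in controls averaged 6.97 ± 0.24 (SD, n = 3) in SUM44 and 7.44 ± 0.31 in LCCTam. Within LCCTam they stood at 7.12, 7.46 and 7.74 in replicates 1, 2 and 3. The GAPDH control probe sets for the 3' and 5' ends of the transcript differed by -0.06 to 0.2 in SUM44 and by 0 to 0.11 in LCCTam. Those of ACTB differed by -0.11, -0.05 and -0.11 in SUM44 replicates 1, 2 and 3 and by 0.08, -0.05 and 0.21 in LCCTam replicates 1, 2 and 3.

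**Figure D1:**
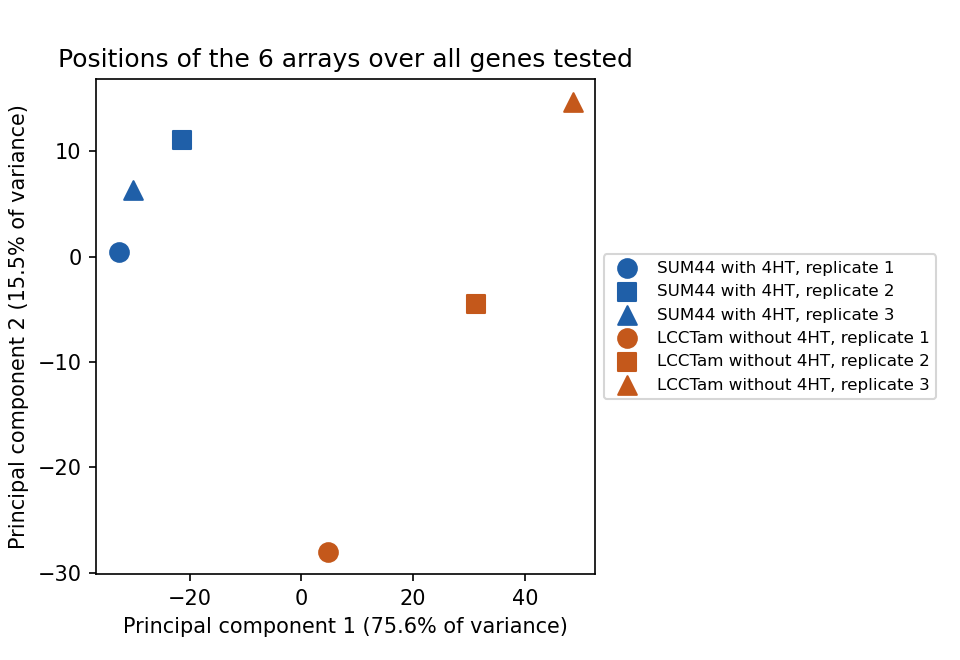
Each point is 1 array, placed by its scores on the first and second principal components of 11963 genes. The SUM44 arrays lie at -32.7 to -21.4 on the first component and the LCCTam arrays at 4.7 to 48.5.

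Transcripts of several secreted and steroid-handling proteins that were abundant in SUM44 were far lower in LCCTam. SCGB2A2 (mammaglobin A, a secretoglobin of the mammary epithelium) was at 12.34 ± 0.19 (SD, n = 3) in SUM44 and 4.99 ± 0.17 in LCCTam, 163-fold lower (adjusted p = 8.12e-07). APOD, a secreted lipocalin that carries small lipids, was 45.1-fold lower (-5.50 ± 0.18 SE). AKR1C2 (-5.41 ± 0.12), AKR1C1 (-5.09 ± 0.11) and AKR1C3 (-4.98 ± 0.14), ketosteroid reductases, were 42.5-, 34- and 31.5-fold lower. DNAJC15, a co-chaperone of the mitochondrial inner membrane, was 36.9-fold lower. In the other direction, CPB1, a carboxypeptidase best known from the pancreas, rose from 5.33 ± 0.24 to 10.82 ± 0.21, 45.1-fold (adjusted p = 3.86e-06).

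SPARC, a secreted matrix glycoprotein, was 14.9-fold higher in LCCTam (3.89 ± 0.15). HSD17B2, which oxidises estradiol to estrone, was 10.3-fold higher (3.36 ± 0.14). DDIT4, an inhibitor of mTOR signalling, was 9.51-fold higher, ASNS (asparagine synthetase) 8.11-fold and CBS (cystathionine beta-synthase, an enzyme of cysteine synthesis) 7.84-fold. These 12 genes had the largest differences in either direction among called genes, and for each of them all LCCTam arrays lay on one side of all SUM44 arrays. AKR1C1 and AKR1C2 are near-identical paralogs measured by probe sets marked as able to bind related transcripts, so their separate values are uncertain. Dimmer probe sets of AKR1C1 and SPARC gave -1.44 and 2.28. The lower level of SCGB2A2 (4.99), DNAJC15 (5.06), CPB1 (5.33) and CBS (5.50) lay below 5.93, the lower quartile of gene means, where signal could not be told from background because no detection calls were used here, so their folds are not exact.

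**Figure D2:**
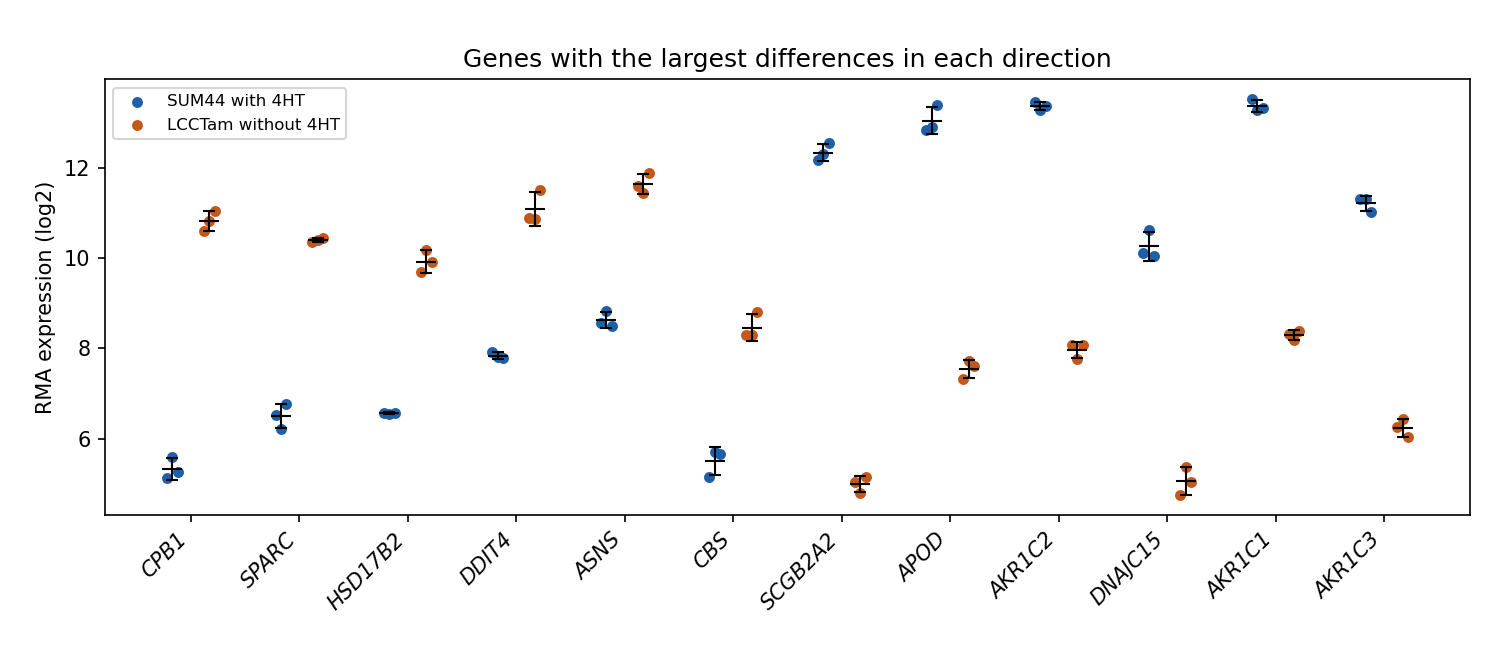
Each point is the log2 expression level of 1 array for the 12 genes with the largest differences, with lines at the group means and bars of 1 SD. SCGB2A2 stands at 12.34 in SUM44 and 4.99 in LCCTam, and CPB1 at 5.33 and 10.82.

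In all, 1888 of the 11963 genes differed at adjusted p under 0.05 by the moderated test of limma, 1098 higher and 790 lower in LCCTam. Of these, 585 differed by at least 2-fold, 228 higher and 357 lower. An unadjusted p under 0.05 was reached by 3753 of the 11963. Counts of list members below are to be read beside these shares of all genes. The groups did not overlap at 4232 genes, or 35.4%, where chance gives 10% for 3 arrays against 3. Other probe sets of the called genes had the sign of the one tested in 1128 of 1254 cases. Among genes named by the rule fixed in advance, 1 or more dimmer probe sets were not called for TGFBR2 (-0.34), NR2F6 (0.45 and 0.10), SLC7A11 (0.98 and 0.65), FN1 (0.25 and -0.13, beside 3 others that were), BAX (0.81) and RELA (0.40), and one of MUC1 was lower by -1.08. The count was 805, 864 and 751 without SUM44 replicates 1, 2 and 3, and 4241, 757 and 1769 without LCCTam replicates 1, 2 and 3. The count differing by at least 2-fold was 1168 without LCCTam replicate 1. Of 147 called members of the fixed gene lists, 74, 77 and 68 remained called without SUM44 replicates 1, 2 and 3, and 147, 76 and 131 without LCCTam replicates 1, 2 and 3.

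ESR1, the gene of estrogen receptor alpha, was lower in LCCTam, at 11.62 ± 0.18 (SD, n = 3) in SUM44 and 10.22 ± 0.53 in LCCTam, a 2.64-fold difference (-1.40 ± 0.25, adjusted p = 0.0109). That is the value of its brightest probe set, and the size depended on the probe set. Of 8 dimmer ones, 4 gave -0.43 to -0.75 (adjusted p = 0.0134 to 0.0496 among all probe sets) and 4 gave -0.07 to 0.05 and were not called, and the mean of its probe sets gave -0.42. TFF1, a secreted trefoil peptide and classical estrogen-induced gene, was higher by 1.30 ± 0.15 (adjusted p = 0.00191). GATA3, a transcription factor of luminal breast cells, was higher by 1.11 ± 0.13 (adjusted p = 0.00174). FOXA1, which opens chromatin for the receptor, differed by 0.22 ± 0.10 (adjusted p = 0.196) and PGR, the progesterone receptor, by -0.21 ± 0.12 at a dim signal of 4.22 and 4.01 (adjusted p = 0.292). Both were called with array weights, which did not converge (adjusted p = 0.00208 for FOXA1, range 0.00208 to 0.456 over the alternatives, and 0.00819 for PGR, range 0.00819 to 0.582). The probe set used for GREB1, a receptor cofactor induced by estrogen, differed by 0.05 ± 0.15 (adjusted p = 0.858), while a dimmer probe set of GREB1 was lower by -1.53 ± 0.19 (adjusted p = 0.00285 among all probe sets). With the mean of its probe sets GREB1 was called lower (-0.44, adjusted p = 0.0441, range 0.0441 to 0.981 over the alternatives). Its difference was also negative, but not called, after cyclic loess (-0.04), without LCCTam replicate 3 (-0.1) and with the axis score as a covariate (-0.25). The ESR1 call was lost without SUM44 replicate 1 (adjusted p = 0.0548) and without SUM44 replicate 3 (0.0583), in a range of 4.66e-06 to 0.0583 over the alternatives.

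**Figure D3:**
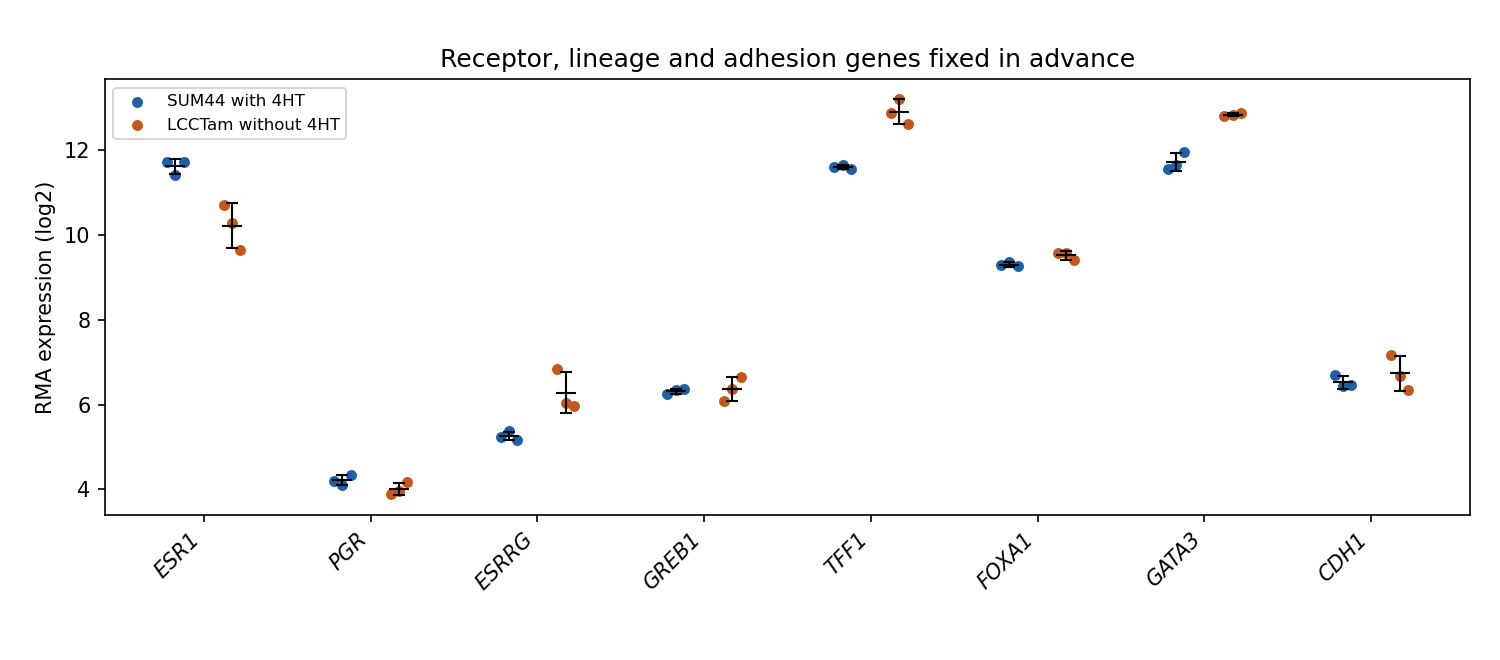
Each point is the log2 expression level of 1 array for the 8 genes named in advance, with lines at the group means and bars of 1 SD. ESR1 lies at 11.62 in SUM44 and 10.22 in LCCTam, and TFF1 at 11.61 and 12.91.

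Among estrogen-induced targets of the receptor, members moved both ways. Of 33 measured, 9 were higher, 6 lower and 18 not called, and adjusted over the list alone 10 were higher and 8 lower. Higher members included TFF1, CELSR2 (an atypical cadherin, 1.26 ± 0.12) and KRT13 (a keratin, 1.35). Lower members included IL17RB, an interleukin 17 receptor (-3.17 ± 0.16), and NRIP1, a corepressor of nuclear receptors (-2.52). The list's median was 0.05 and its mean -0.04, and camera gave a downward direction (adjusted p = 0.851). Of 28 measured genes of luminal identity, 6 were higher, 8 lower and 14 not called, with 8 higher and 8 lower adjusted over the list alone (camera adjusted p = 0.37). MUC1, a surface mucin, fell by 2.45 on the log2 scale and the keratin KRT8 by 1.09, while SCUBE2, a secreted and membrane-bound glycoprotein, rose by 1.64 and the trefoil peptide TFF3 by 0.99. With SUM44 replicates 1, 2 and 3 and then LCCTam replicates 1, 2 and 3 left out in turn, called members numbered 7, 7, 6, 15, 6 and 16 for the receptor targets and 7, 9, 7, 16, 8 and 14 for the luminal list.

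ESRRG, an orphan receptor related to the estrogen receptors, was 2.02-fold higher in LCCTam, at 5.26 ± 0.10 (SD, n = 3) and 6.28 ± 0.48 (1.02 ± 0.23, adjusted p = 0.0233), a dim signal. A still dimmer probe set of ESRRG gave 2.21 ± 0.51 (adjusted p = 0.0299 among all probe sets). Of 36 nuclear receptors and coregulators, 5 were higher (ESRRG, NR2F6, RXRB, VDR and NR1H3), 4 lower (ESR1, NRIP1, NR1D2 and NR3C2) and 27 not called. The counts were 5 and 4 adjusted over the list alone as well, and the median was 0.08, the mean -0.06 and the camera direction downward (adjusted p = 0.851). NR3C2, the mineralocorticoid receptor, fell by 0.83 and NR2F6, an orphan receptor, rose by 0.66. The ESRRG call was lost without SUM44 replicates 1, 2 and 3 (adjusted p = 0.0914, 0.0692 and 0.0984) and LCCTam replicate 2 (0.0566), in a range of 6.25e-05 to 0.0984 over the alternatives. In all, called members of the list numbered 0, 4, 1, 12, 3 and 8 without SUM44 replicates 1, 2 and 3 and LCCTam replicates 1, 2 and 3. NR2F6 lost its call without SUM44 replicates 1 and 3 and LCCTam replicate 2 (0.0504, 0.0561 and 0.0552, range 9.08e-06 to 0.0888), and NR3C2 without SUM44 replicates 1 and 2 (0.0553 and 0.0522, range 7.79e-05 to 0.0553).

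Genes of AP-1 and MAPK output, the transcription factors and feedback regulators downstream of growth factor signals, were mostly higher where called. Of 28 measured, 10 were higher, 3 lower (IER3, FOSL2 and EGR1) and 15 not called, and 11 were higher and 3 lower adjusted over the list alone. MYC, a transcription factor of cell growth, rose by 1.69 ± 0.10, DUSP5, a phosphatase of ERK, by 1.48 ± 0.13, ATF3, a stress-induced factor, by 1.86 and JUNB, an AP-1 subunit, by 0.87. As a list they did not pass camera (adjusted p = 0.0958), and the medians in LCCTam replicates 1, 2 and 3 were 0.04, 0.18 and 0.28. Of 41 growth factor receptors and ligands, 3 were higher (IGFBP3, ERBB2 and VEGFA), 7 lower and 31 not called, with 4 higher and 8 lower adjusted over the list alone. IGFBP3, a carrier of insulin-like growth factors, rose by 2.08, while TGFBR2, a TGF-beta receptor, fell by 1.57 and ERBB4, a receptor of the EGFR family, by 1.35. This list's median was 0.1, its mean -0.02 and its camera direction downward (adjusted p = 0.851). Without SUM44 replicates 1, 2 and 3 and LCCTam replicates 1, 2 and 3, called members numbered 7, 7, 7, 16, 7 and 12 for AP-1 and MAPK output and 6, 5, 4, 12, 4 and 11 for growth factors.

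Genes of cell proliferation were mostly higher in LCCTam where called with all 6 arrays. Of 44 measured, 15 were higher, 1 lower (GINS1, a subunit of the replicative helicase) and 28 not called, and adjusted over the list alone 19 were higher and 2 lower. AURKB, a kinase of chromosome segregation, rose by 1.23 ± 0.13, BIRC5, its partner in mitosis, by 1.16 ± 0.13, MCM5, a subunit of the replicative helicase, by 1.03, and FOXM1, a transcription factor of late cell cycle genes, by 0.83. Over all members the median was 0.31 (camera adjusted p = 0.0162, and adjusted p = 0.828 with an estimated correlation, the highest of a range from 2.32e-10 over the alternatives tested with camera). Its medians in LCCTam replicates 1, 2 and 3 were 0.4, 0.46 and 0.24. The list's call was lost without SUM44 replicate 2 (adjusted p = 0.0586) and LCCTam replicate 1 (0.369), and 11, 7, 6, 29, 10 and 18 members were called without SUM44 replicates 1, 2 and 3 and LCCTam replicates 1, 2 and 3. The 29 without LCCTam replicate 1 were 21 higher and 8 lower, against 15 and 1 with all arrays.

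Of the genes of tamoxifen metabolism and drug transport, those called with all 6 arrays were lower in LCCTam. Of 31 measured, 9 were lower, none was higher and 22 were not called, with the same counts adjusted over the list alone, and 12 members had an unadjusted p under 0.05. Beside AKR1C1, AKR1C2 and AKR1C3, they were NQO1, a quinone reductase (-1.01), GSTM3, a glutathione transferase (-1.22), ABCC2, an export pump (-0.77), SULT1A1, a sulfotransferase that acts on 4HT (-0.70), AHR, the dioxin receptor (-0.52), and CYP1B1, an estrogen hydroxylase induced by it (-1.61). The median of the list was -0.13 and its mean -0.70 (camera adjusted p = 6.94e-05, and adjusted p = 0.318 with an estimated correlation). Without the 3 AKR1C genes, an alternative chosen after seeing the data, camera gave adjusted p = 0.0162, within a range of 2.26e-07 to 0.318 over the alternatives tested with camera. The medians in LCCTam replicates 1, 2 and 3 were -0.16, -0.09 and -0.06. The called members numbered 6 without each of SUM44 replicates 1, 2 and 3 and LCCTam replicate 2, and without LCCTam replicate 1 there were 9 lower and 1 higher.

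Genes of the unfolded protein and amino acid response were more often higher than lower where called. Of 34 measured, 14 were higher, 4 lower and 16 not called, and adjusted over the list alone 17 were higher and 9 lower. The higher members included ASNS (3.02 ± 0.15), DDIT4 (3.25 ± 0.18), ATF4, the transcription factor that drives the amino acid response (1.72), CHAC1, an enzyme that degrades glutathione (2.63), and PHGDH, the first enzyme of serine synthesis (1.62). The lower members were chaperones and folding enzymes of the endoplasmic reticulum, HSP90B1 (-1.28), DNAJC3 (-1.09), CANX (-0.98) and PDIA3 (-0.52). These genes had a median of 0.26 (camera adjusted p = 0.0337, and adjusted p = 0.318 with an estimated correlation, the highest of a range from 0.000403 over the alternatives tested with camera), and it was 0.17, 0.23 and 0.32 in LCCTam replicates 1, 2 and 3. The call was lost without SUM44 replicate 2 (adjusted p = 0.0586) and LCCTam replicate 1 (0.178). No lower member was called without SUM44 replicates 1, 2 or 3 or LCCTam replicate 2, and 8 were without LCCTam replicate 1.

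Of 38 genes of glutamate signalling and transport, 4 were higher, 1 lower and 33 not called, and adjusted over the list alone 3 were higher and 1 lower (camera adjusted p = 0.199). All those called act in amino acid transport or aminotransfer, and none was a glutamate receptor. SLC1A4, a neutral amino acid carrier, rose by 1.65 ± 0.11, SLC7A11, which exchanges cystine for glutamate, by 1.73 ± 0.18, SLC1A5, a glutamine carrier, by 1.06 and GOT2, a mitochondrial aminotransferase, by 0.39. SLC1A1, a glutamate carrier, fell by 0.91. The list's median was -0.05, 0.17 and 0.36 in LCCTam replicates 1, 2 and 3. SLC7A11 lost its call with the mean of its probe sets (adjusted p = 0.0735, range 1.01e-06 to 0.0735), and without SUM44 replicates 1, 2 and 3 and LCCTam replicates 1, 2 and 3 called members numbered 2, 3, 3, 11, 3 and 4.

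Of the genes of cholesterol synthesis, those called with all 6 arrays were lower in LCCTam. Of 21 measured, 6 were lower, none was higher and 15 were not called, with 8 lower adjusted over the list alone, and 9 had an unadjusted p under 0.05. HMGCS1, which makes HMG-CoA, fell by 1.33 ± 0.22, and the later enzymes MSMO1 by 1.28 ± 0.19, IDI1 by 1.37 and SC5D by 1.94. Over the list the median was -0.09 and the mean -0.38 (camera adjusted p = 0.0162, and adjusted p = 0.318 with an estimated correlation, the highest of a range from 0.0036 over the alternatives tested with camera). Its medians in LCCTam replicates 1, 2 and 3 were -0.25, -0.06 and -0.14. Of 23 genes of fatty acid synthesis, 2 were higher (the elongase ELOVL2, 0.73, and the lipase PNPLA3, 0.60), 2 lower (the elongase ELOVL5, -1.03, and the desaturase SCD, -0.75) and 19 not called, with the same counts adjusted over the list alone (camera adjusted p = 0.575). The cholesterol list's call was lost without LCCTam replicate 1 (adjusted p = 0.0979), and its called members numbered 2, 3, 2, 9, 2 and 7 without SUM44 replicates 1, 2 and 3 and LCCTam replicates 1, 2 and 3. The 9 without LCCTam replicate 1 were 8 lower and 1 higher, and the 7 without LCCTam replicate 3 were 6 lower and 1 higher. In the same order of arrays, those of fatty acid synthesis numbered 1, 2, 1, 9, 2 and 5, with PNPLA3 not called without SUM44 replicates 1 and 3 and LCCTam replicate 2 (adjusted p = 0.068, 0.0694 and 0.0725, range 3.63e-05 to 0.0725).

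Genes of hypoxia and glycolysis were more often lower than higher where called. Of 32 measured, 2 were higher, 9 lower and 21 not called, and adjusted over the list alone 3 were higher and 10 lower. LDHA, which turns pyruvate to lactate, fell by 1.03, PGK1, a glycolytic kinase, by 0.48 and MXI1, an antagonist of MYC, by 1.35 ± 0.16. P4HA1, a collagen prolyl hydroxylase, fell by 1.91. The higher members were PGM1, which interconverts glucose phosphates for glycogen (2.10 ± 0.12), and the angiogenic factor VEGFA (0.59). Members had a median of -0.13 (camera adjusted p = 0.0291, and adjusted p = 0.318 with an estimated correlation, the highest of a range from 0.0178 over the alternatives tested with camera), and it was -0.18, -0.03 and -0.17 in LCCTam replicates 1, 2 and 3. The call was lost without SUM44 replicate 3 (adjusted p = 0.0502) and LCCTam replicate 1 (0.133), and called members numbered 3, 4, 3, 14, 3 and 7 without SUM44 replicates 1, 2 and 3 and LCCTam replicates 1, 2 and 3.

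**Figure D4:**
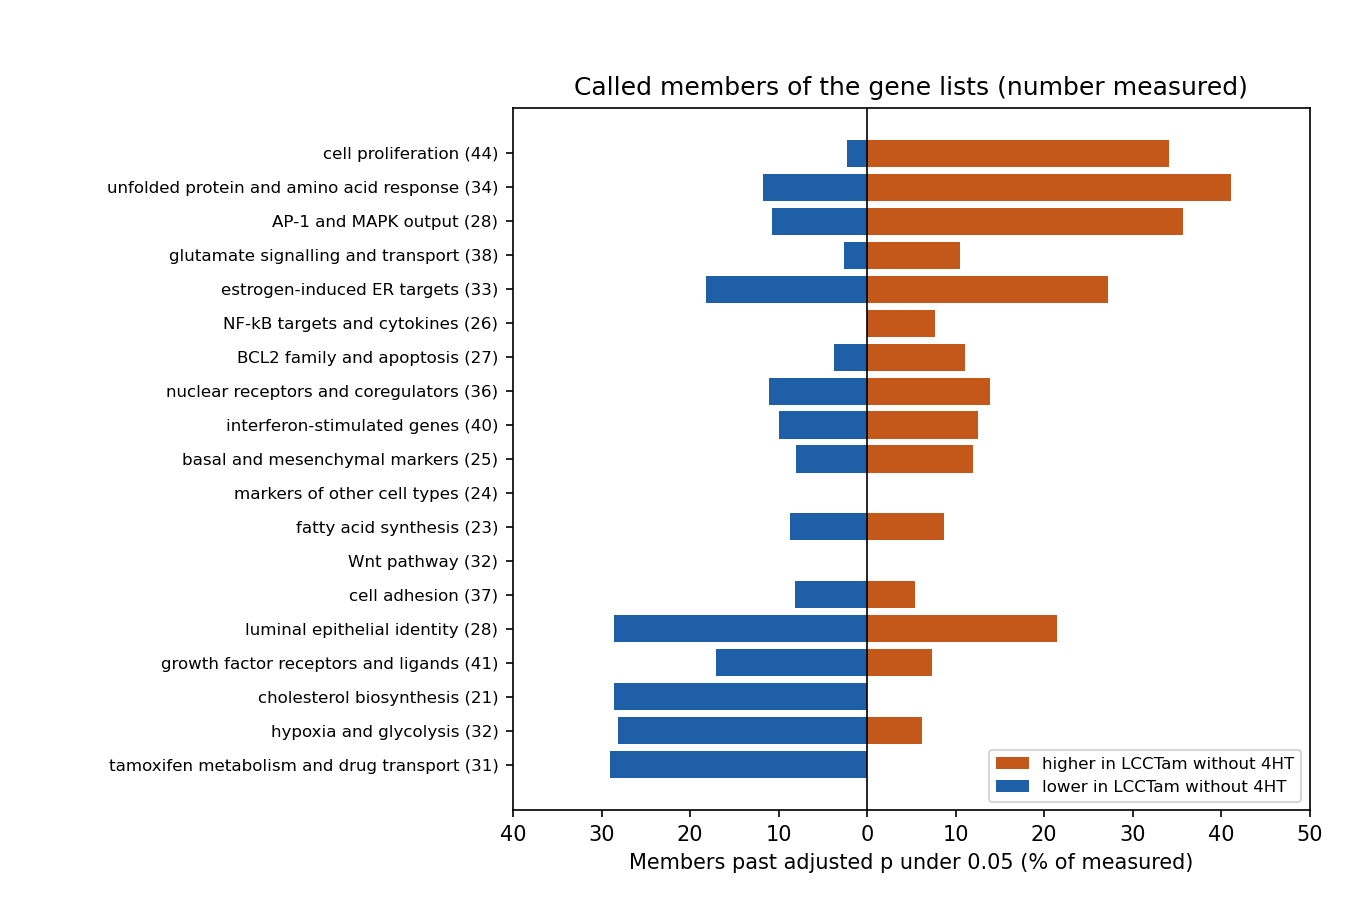
Bars give the share of each gene list's measured members, in percent, that were called higher (right) or lower (left) in LCCTam. Proliferation had 15 higher and 1 lower of 44 members, and tamoxifen metabolism 9 lower of 31.

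Interferon-stimulated genes moved both ways. Of 40 measured, 5 were higher, 4 lower and 31 not called, and adjusted over the list alone 5 were higher and 7 lower. The higher members were PSMB9 (1.31 ± 0.11) and PSMB8 (0.64), subunits of the immunoproteasome, the peptide transporter TAP1 (0.69), the peptide-presenting HLA-E (0.42) and USP18, which removes ISG15 from proteins (0.97). The lower ones were the antiviral proteins IFITM3 (-2.37 ± 0.14), ISG15 (-1.01), IFI27 (-0.89) and OAS1 (-0.47). The list's median was 0.01, its mean -0.01 and its camera direction downward (adjusted p = 0.851). Of 26 NF-kB targets and cytokines, the transcription factor subunit RELA (0.46) and the inhibitor NFKBIE (0.63) were higher and 24 were not called (camera adjusted p = 0.34). Neither passed adjusted over the list alone, where limma called 0. An unadjusted p under 0.05 was found for 5 members, a smaller share than the 3753 of 11963 over all genes. Called interferon-stimulated members numbered 6, 6, 6, 15, 6 and 9 without SUM44 replicates 1, 2 and 3 and LCCTam replicates 1, 2 and 3, and those of NF-kB numbered 0, 0, 0, 5, 0 and 1. RELA had adjusted p = 0.168, 0.11 and 0.124 without SUM44 replicates 1, 2 and 3 and 0.157 and 0.0773 without LCCTam replicates 2 and 3 (range 9.31e-05 to 0.168), and NFKBIE had 0.119, 0.126 and 0.16 without SUM44 replicates 1, 2 and 3 and 0.0923 without LCCTam replicate 2 (range 0.00044 to 0.16).

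Of 27 genes of the BCL2 family and apoptosis, 3 were higher, 1 lower and 23 not called, with the same counts adjusted over the list alone. BAX, which permeabilises mitochondria, rose by 0.80 ± 0.14, BIK, a BH3-only killer protein, by 0.63 ± 0.15 and CASP9, an initiator caspase, by 0.80, while BCL2L2, a survival protein, fell by 0.43. The median and mean were 0.03, and camera, which compares the list with other genes, gave a downward direction (adjusted p = 0.851) beside a median of 0.077 for all genes. Called members numbered 1 without each of SUM44 replicates 1, 2 and 3 and LCCTam replicate 2, and 11 without LCCTam replicate 1. BIK lost its call without SUM44 replicates 1, 2 and 3 and LCCTam replicate 2 (adjusted p = 0.0993, 0.0736, 0.122 and 0.102, range 6.21e-05 to 0.122).

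CDH1, the gene of E-cadherin, which lobular breast carcinomas often lack, was at 6.52 ± 0.14 (SD, n = 3) in SUM44 and 6.73 ± 0.41 in LCCTam (0.21 ± 0.20, adjusted p = 0.522), with a negative difference without LCCTam replicate 1 (adjusted p = 0.971, range 0.00315 to 0.971). The lowest of these came with each array's score on the main axis of spread within groups as a covariate, where CDH1 was higher by 0.65. That alternative was chosen after seeing the data, and its p-values tend to be too small because the score came from the same arrays. Of 37 genes of cell adhesion, 2 were higher (ITGA5, a fibronectin receptor, 0.61, and NECTIN2, 0.65), 3 lower and 32 not called, with 4 higher and 5 lower adjusted over the list alone (camera adjusted p = 0.134). CDH3, the gene of P-cadherin, fell by 1.81 ± 0.12, DSG2, a cadherin of desmosomes, by 1.29 ± 0.11 and CTNNA1, the catenin that links cadherins to actin, by 0.48. Of 25 basal and mesenchymal markers, 3 were higher (SPARC, FN1 and TWIST1), 2 lower (CD44 and SNAI1) and 20 not called, with the same counts adjusted over the list alone (camera adjusted p = 0.851). FN1, the gene of the matrix protein fibronectin, rose by 0.96 ± 0.17, and its call was lost without SUM44 replicates 2 and 3 (adjusted p = 0.053 and 0.0589, range 4.96e-06 to 0.0589). Without SUM44 replicates 1, 2 and 3 and LCCTam replicates 1, 2 and 3, called members numbered 2, 3, 2, 17, 2 and 7 for adhesion and 3, 1, 2, 9, 3 and 5 for the basal and mesenchymal list.

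No gene of the Wnt pathway, of 32 measured, was called by limma, over all genes or adjusted over the list alone, while 5 had an unadjusted p under 0.05 (camera adjusted p = 0.851, fry adjusted p = 0.412). The 5 were RNF43, LRP5, LGR4, FZD3 and FZD7. Over all 11963 genes tested, 3753 had an unadjusted p under 0.05, a larger share than in this list or the next. None of 24 markers of other cell types was called either, over all genes or adjusted over the list alone, and 3 had an unadjusted p under 0.05, the monocyte marker CD14, the adipocyte hormone ADIPOQ and the globin HBB (camera adjusted p = 0.851, fry adjusted p = 0.557). Their median was -0.04, 0.08 and 0.23 in LCCTam replicates 1, 2 and 3. Without LCCTam replicate 1, 5 Wnt members and 2 markers of other cell types were called, and without LCCTam replicate 3, 1 Wnt member was.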

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

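The test of mixed SUM44 material was chosen only after the result was seen, and the fit with the axis score as a covariate was added after seeing the data. As the score was taken from the same arrays, gene p-values of that fit tend to be too small. The other tests of this part were planned before their results were seen, although the pattern along gene density was noticed in the same data.

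Among 3150 probe sets without a single gene name, which took no part in the gene test, 336 passed an adjusted p under 0.05 in the fit of all probe sets, 199 higher and 137 lower in LCCTam. The poly-A spike-in controls, added to the RNA before labelling, averaged 7.44 in the LCCTam arrays, above the highest SUM44 array at 7.15, with LCCTam replicate 1 at 7.12 inside the SUM44 range of 6.70 to 7.15. The hybridisation controls, added after labelling, averaged 9.50 ± 0.19 (SD, n = 3) in SUM44 and 9.63 ± 0.10 in LCCTam.

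Of the 10 splits of the 6 arrays into 3 and 3, the real one called 1888 genes and was the only 1 to call as many. The highest of the others called 0 by limma, with 14 to 1766 genes at an unadjusted p under 0.05, against 3753 in the real one. Each of the others puts arrays of both groups into each set of 3. The group difference then adds to the spread within sets, which lowers their counts. With 10 splits, a share under 0.05 cannot be reached.

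Coding gene density of the chromosome was set against 4 differences over 23 chromosomes. For LCCTam replicate 3 minus replicate 1, Pearson r was 0.82 (permutation p = 1e-05, the smallest possible) and 0.93 without chromosomes 19 and 17. For SUM44 replicate 2 minus its group, Spearman rho was 0.56 (permutation p = 0.0066, adjusted 0.0083) and r 0.61 (permutation p = 0.001), and 0.45 without those chromosomes. For LCCTam minus SUM44, rho was 0.77 (permutation p = 7e-05, adjusted 0.00014) and r 0.73 (permutation p = 5e-05), and 0.71 without them. With the axis score as a covariate, rho was 0.54 (permutation p = 0.0083, adjusted 0.0083) and r 0.52 (permutation p = 0.013), and 0.42 without them, and that fit called 1898 genes, of which 1460 were called without the covariate. Chromosomes are not independent samples.

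The LCCTam arrays spread along 1 axis that held 74.6% of the spread within groups, with scores of -16.2, 19.4 and 45.1 for replicates 1, 2 and 3 and -23.2, -7.6 and -17.5 for SUM44, and 866 genes were over 1 log2 unit lower and 10 over 1 higher in replicate 3 than in replicate 1. SUM44 RNA or cells mixed into replicate 1 were argued against as the whole source by the 20 genes highest in SUM44. They showed a median SUM44 share of 0.1% (quartiles -0.6% and 2.5%). To set replicate 1 apart, 457 genes, which include HNMT, NAT1 and NRIP1 of the 20, would need a median of 83.8%. These were picked as over 1 log2 unit higher in both replicate 1 and SUM44 than in replicates 2 and 3, which itself raises their share. Among the 20, GJA1, NAT1, NRIP1 and HNMT nevertheless stood at 22% to 50.4%. A labelling bias with base composition may contribute, since the difference between replicates 3 and 1 rose with gene density (rho = 0.95, permutation p = 1e-05, the smallest possible, adjusted 4e-05), and SUM44 replicate 2 lay below its group at 96.2% of the 866 genes against 45% of all genes. Base composition itself was not measured, and a difference in the state of the cultures, which no label describes, stays open.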

How the results depend on the processing

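The fit with the axis score as a covariate and the list without AKR1C genes were chosen after seeing the data, and the other alternatives before. Calls with the axis score are no independent check, since the score was taken from the same arrays. LCCTam replicate 1 scored -16.2, inside the SUM44 range of -23.2 to -7.6, so that fit's group difference rests largely on this replicate. No called gene changed sign in any of the gene-level alternatives. Of 147 called list members, 147 kept their call with array weights and without LCCTam replicate 1, 135 with the mean of probe sets, 125 after cyclic loess and 120 with the axis score. Without SUM44 replicates 1, 2 and 3 and LCCTam replicates 2 and 3, 74, 77, 68, 76 and 131 kept it. The intensity trend with robust fitting (1787 genes called) ended the call of RELA (0.0559). It did not enter the list tests, which were the same as in the main fit by construction. Median centring (1861 genes called) changed no list call. Higher genes made up 58.2% of the calls and 51.6% after cyclic loess. Array weights put nearly all the weight of LCCTam on replicate 2 (weights of 0.17, 43.86 and 0.17) and did not converge, so their counts are not reliable. Dim genes are limited by signal over background, which the values do not give. Except where fewer genes or arrays entered by construction, the cause was not tested.

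Over the arrays left out in turn, called genes ranged from 751 to 4241, higher genes from 430 to 2237, lower genes from 303 to 2004 and genes at 2-fold or more from 405 to 1168. The adjusted p ranged from 7.84e-06 to 0.369 for proliferation, from 0.00697 to 0.178 for the unfolded protein and amino acid response, from 0.0178 to 0.133 for hypoxia and glycolysis and from 0.0036 to 0.0979 for cholesterol synthesis. It ranged from 0.73 to 0.951 for markers of other cell types, 0.438 to 0.956 for interferon-stimulated genes, 0.841 to 0.999 for the BCL2 family, 0.172 to 0.971 for CDH1 and 0.257 to 0.981 for GREB1, which each turned direction without at least 1 array.

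With every probe set as its own unit, 3002 were called, 1677 higher and 1325 lower, and 933 by at least 2-fold. AP-1 and MAPK output then passed (adjusted p = 0.0403), the unfolded protein (0.288) and hypoxia (0.0568) lists no longer did, and nuclear receptors (0.929) and basal markers (0.999) turned direction. With the mean of probe sets, the unfolded protein (0.0723) and hypoxia (0.0638) lists, NR2F6 (0.0888) and SLC7A11 (0.0735) lost their calls. GREB1 turned and was called lower (0.0441). Array weights called 7021 genes, 4316 higher and 2705 lower, 894 by at least 2-fold, and ended the calls of cholesterol (0.0815), unfolded protein (0.207) and hypoxia (0.0837), and called FOXA1 (0.00208) and PGR (0.00819). After cyclic loess GREB1 (0.838), the Wnt pathway (0.948) and other cell types (0.948) turned, and ESRRG (0.0635), RELA (0.0619) and NFKBIE (0.0594) lost their calls. Among genes brighter than the median, cholesterol (0.0593) and unfolded protein (0.0829) lost their calls and basal markers (0.509), nuclear receptors (0.64), the BCL2 family (0.804) and Wnt (0.969) turned. Among genes at 6 or more, unfolded protein (0.0591) and hypoxia (0.0579) lost theirs and nuclear receptors (0.739) turned. At an adjusted p under 0.01, 723 genes were called, 423 higher and 300 lower. With the axis score as a covariate, other cell types (0.685), Wnt (0.841), basal markers (0.841), the BCL2 family (0.985), estrogen-induced targets (0.871) and GREB1 (0.189) turned, and BIK (0.0665), RELA (0.147) and NFKBIE (0.147) lost their calls.

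With an estimated correlation, adjusted p was 0.318 for cholesterol, tamoxifen metabolism, hypoxia and unfolded protein and 0.828 for proliferation, so none of the 5 list calls held. The estimated correlations were 0.2 for proliferation, 0.1 for tamoxifen metabolism, 0.05 for cholesterol, 0 for hypoxia and -0.02 for unfolded protein. Those of hypoxia and unfolded protein lay below the preset 0.01, so a higher correlation did not end their calls. This form of camera uses the 4 residual degrees of freedom of the fit and has far less power. The lost calls therefore do not decide whether these lists differed. Fry's directional test, which does not compare a list with other genes, passed unfolded protein (0.000117), tamoxifen metabolism (0.00106) and hypoxia (0.0176). It gave 0.075 for proliferation and 0.0595 for cholesterol. It also passed AP-1 (0.0176) and adhesion (0.0176), and turned estrogen-induced targets (0.147), nuclear receptors (0.422), interferon-stimulated genes (0.958) and the BCL2 family (0.397). Its test of change in either direction does not compare a list with other genes either. It says little of a single list where 3753 of 11963 genes had an unadjusted p under 0.05. This test passed the 5 lists called by camera. Of the others it passed estrogen-induced targets (2.56e-06), luminal identity (2.56e-06), basal markers (6.79e-06), nuclear receptors (0.00357), AP-1 (2.38e-05), growth factors (6.12e-05), fatty acids (0.000154), glutamate (0.000168), the BCL2 family (0.0276), interferon-stimulated genes (1.15e-05), NF-kB (0.0393) and adhesion (6.12e-05). Of chromosome segments, 75 of 237 were called at 50 genes (31 to 74 at chromosome ends), 37 higher and 38 lower, 92 of 475 at 25 (55 and 37), 47 of 121 at 100 (22 and 25), and 25 of 237 with the axis score (17 and 8). With an estimated correlation camera called 0 of the 237, the smallest adjusted p being 0.45, and 21 had an unadjusted p under 0.05. That 0 decides nothing about the segments, given the same 4 degrees of freedom.

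The replicate numbers did not pair all the arrays. Deviations of same-numbered arrays from their group means correlated over genes at 0.49, 0.35 and -0.05. LCCTam replicates 1 and 2 correlated best with the SUM44 array of the same number, and LCCTam replicate 3 with SUM44 replicate 2 (0.49). With 3 arrays per group and 1 main axis of spread, these values cannot settle whether the arrays were paired. The replicate block called 2152 genes and ended the call of the unfolded protein list (adjusted p = 0.0971) and of NFKBIE (0.0563).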

Other observations

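The lists of further NRF2 targets and amino acid response genes were put together after the fixed lists had been seen, and their own members had not been looked at. The fit with the axis score was added after seeing the data. The other tests of this part were planned before their results were seen.

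Several enzymes of redox defence that no fixed list held were lower in LCCTam. AKR1B10, an aldo-keto reductase, was 8.13-fold lower (-3.02 ± 0.12 SE, n = 3, adjusted p = 1.23e-05) and HMOX1, which breaks down haem, 6.17-fold lower (-2.63 ± 0.23, adjusted p = 0.000541). Both were chosen after their values were seen. Of 22 further measured targets of NRF2, the transcription factor of the oxidative stress response, 9 were lower and 2 higher. TXNRD1, a thioredoxin reductase, fell by 2.38, ALDH3A2, an aldehyde dehydrogenase, by 1.60, GCLC, of glutathione synthesis, by 1.33 and UGDH, which makes the sugar for glucuronidation, by 1.26, while BLVRB (0.61) and MAFG (0.57) rose. Without SUM44 replicates 1, 2 and 3 and LCCTam replicate 2 in turn, 7 of these targets were lower and 0 higher by limma. Without LCCTam replicate 1, 10 were lower and 4 higher, and without LCCTam replicate 3, 9 and 1. BLVRB and MAFG each lost their call in 8 of 16 alternatives (adjusted p from 0.000321 to 0.158 and from 0.000584 to 0.139), and GCLM and PRDX1 in 4 each (up to 0.111 and 0.0748).

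Of 22 further genes of the amino acid response, 13 were higher and none was lower. PSPH, the last enzyme of serine synthesis, rose by 2.12, SLC7A1, a carrier of cationic amino acids, by 1.87, CEBPG, a partner of ATF4, by 1.69, and the tRNA synthetases YARS1 by 1.47 and AARS1 by 1.44. Leaving out each array in turn gave 11 to 14 higher, and 3 were lower without LCCTam replicate 1.

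It may be that the lower AKR1C genes, AKR1B10, HMOX1 and NQO1 belong to a lower output of the NRF2 programme in LCCTam, although these genes were picked because they were lower. SLC7A11, also a known target of NRF2, went the other way (1.73, adjusted p = 0.00121, range 1.01e-06 to 0.0735 over the alternatives). The further targets had a median of -0.32 (camera p = 6.97e-05, p = 0.0124 with an estimated correlation, and 1.45e-06 to 0.00199 over the alternatives run), which is consistent with that. The data do not show whether NRF2 itself differed in activity, and 4HT and cell line differ together.

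A wider amino acid response may likewise account for the higher ASNS, PHGDH, CHAC1 and ATF4. The further genes had a median of 0.98 (camera p = 3.16e-07, p = 0.00567 with an estimated correlation, and 2.22e-12 to 0.000249 over the alternatives run). The supply of amino acids in the cultures was not measured, and a difference in culture state stays open beside a difference between the lines.

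Neighbouring genes shifted together in places. Of 237 runs of 50 neighbouring genes, or 31 to 74 at chromosome ends, 75 were called with camera, 37 higher and 38 lower in LCCTam. With the axis score as a covariate 25 were called, 17 higher and 8 lower, 24 of them in both. That score was taken from the same arrays, so these calls are not an independent check. With runs of 25 genes 55 were higher and 37 lower. With an estimated correlation 0 were called by camera, the smallest adjusted p being 0.45, and 21 had an unadjusted p under 0.05. At 4 residual degrees of freedom that form of camera has little power over 237 runs, so the 0 decides nothing. The runs with the smallest p were higher ones on chromosomes 17, 19, 22 and 16. These held 14.08, 24.78, 8.88 and 9.48 coding genes per Mb, against 2.96 on chromosome 13, while chromosome 11, at 9.68, was not among them. Over chromosomes the group difference itself rose with gene density (rho = 0.77), so such runs cannot all be told apart from that pattern. The density of a whole chromosome does not place runs within it, though. On chromosome 17 only the adjoining runs MRPL58 to TBC1D16 and CCDC40 to QTGAL were called, and the others had camera adjusted p of 0.191 or more. Chromosome 20, at 8.37 coding genes per Mb, held lower runs, DEFB126 to SLC23A2 (mean -0.16) and TMEM230 to CST4 (-0.27). It also held a higher one, MRGBP to PCMTD2 (0.2).

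The axis of spread within LCCTam could account for some of the called runs. Over the called runs, the shift in LCCTam replicate 1 had a median of 0.39 of that in replicates 2 and 3, between the bounds set for and against this, so it stays open. Whether copy number differs between the lines was not measured.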
